A study of Oryza sativa with 6 samples.

How the data were processed

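Transcripts were measured on 6 two-colour Agilent rice arrays, 3 comparing wild-type roots treated with NPA with untreated wild-type roots and 3 comparing untreated iaa13 roots with untreated wild-type roots. Per the labels, seedlings were 20 d old, grew in aerated hydroponic solution, were treated with 0.5 µM NPA for 48 h where treated, and gave root segments taken 15 to 25 mm from the tip. RNA was extracted with RNeasy Plant columns, and 400 ng was labelled with the Quick Amp kit, untreated wild type with Cy5 and the other sample with Cy3 on every array, per the labels' protocols.

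The spot intensities of both dyes were read by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers: a mean pixel intensity per spot, a median intensity of its local background and a processed intensity after background subtraction and dye normalisation. The deposited value table holds a linear ratio of the processed signals, Cy5 over Cy3 (untreated wild type over the other sample), which is not centred. This reading was checked on the 43854 spots of each array, where the deposited ratio and the ratio of the processed signals differed by at most 3.33e-07 on the log2 scale. The column medians of the deposited ratio were 0.931, 0.928 and 0.925 for NPA arrays 1, 2 and 3 and 0.964, 0.985 and 0.963 for iaa13 arrays 1, 2 and 3. The deposited ratio therefore equals the alternative named processed signals.

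Log2 ratios were computed from the mean spot intensities with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8 and statmod 1.5.0). Background was corrected by normexp with an offset of 50, and each array was normalised by loess with its control spots at weight 0. Spots that the scanner software marked as non-uniform or as population outliers, between 121 and 178 per array, were left out, and spots of the same probe were averaged. A probe was kept if it was well above background in at least 1 dye on all 3 arrays of at least 1 group, which kept 32191 of 41908 probes of annotated loci. Of 29690 loci, 21889 had 1 probe; a locus with several was represented by the probe of highest mean intensity, which left 22280 genes. The 2007 control spots and 510 microRNA probes took no part in the gene comparisons. Spike-in RNAs of known ratio gave slopes between 0.888 and 0.904 on the log2 scale with r between 0.987 and 0.993.

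The depth of an array is its signal over background: 68.5% (NPA replicate 1), 70.1% (NPA replicate 2), 69.6% (NPA replicate 3), 74.1% (iaa13 replicate 1), 72.5% (iaa13 replicate 2) and 70.5% (iaa13 replicate 3) of non-control spots were well above background in Cy3. Where the weaker sample of a gene was not well above background on its 3 arrays, a lower bound of the fold change is given in place of the ratio. Putting such genes at their bound moved the median of a list by at most 0.214, in the xyloglucan endotransglycosylases with NPA.

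The comparisons, the tests, the named genes, 39 gene lists and the alternatives were fixed before the data were examined. Limma fitted the means of both groups to the 6 arrays, with 4 residual degrees of freedom, and tested each mean against 0 and their difference, iaa13 minus NPA, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, then with the correlation estimated, and with fry. Adjustment ran over the lists of a comparison, apart for the fixed lists and for 17 lists added after the gene descriptions on the array were read and before any ratio was computed. 7 fixed lists held fewer than 3 measured genes and had no test. Fry's test of a common direction was run beside camera and decided no call.

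Gene names are the descriptions in the array files, which pair each probe with a rice locus and date from an early annotation. The reference table (assembly ASM3414082v1) matched 0 of the loci and 0 of the probe accessions, so no newer name and no coordinate is given. Lists were matched on words in these descriptions, so some hold other genes: the gibberellin list holds ribosomal protein L9 genes, the endoglucanase list a barwin-related gene, the cytochrome P450 list a P450 reductase, and the replication list a ferritin-like gene (Os05g0447700).

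Genes were named by rule: IAA13; for NPA and iaa13 the 8 largest rises and 8 largest falls among genes past the threshold with a description and the same direction on all 3 arrays; for each list up to 3 members of smallest p; for the genes called in both, the 5 with the largest smaller change per direction; and for the difference the 5 largest per direction. Descriptions reading "No Hit" were taken as no description, a reading made after the genes were seen that left out Os11g0117500 and Os02g0560600. Of the list members chosen this way, the text gives a part, mostly those of smallest p. Each named gene given as risen or fallen had that direction on all 3 arrays of its comparison.

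Replicate numbers paired the samples. Per the labels each number marks a biological replicate, and in the data the ratio deviations of same-numbered NPA and iaa13 arrays correlated at 0.517, 0.638 and 0.546, those of Cy5 (wild type) at 0.832, 0.879 and 0.908, and those of Cy3 at 0.0845, 0.0216 and 0.119. The comparisons were fitted without the replicate number, as fixed in advance, and again with it as a block; its values are given only where they change a call or move a count by over 1.5 times. The expected overlap under shared controls came from 20 simulations of unchanged groups.

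The analysis was tested on simulated data with the real arrays' intensities and 200 changed genes each for NPA and iaa13, so that 130, 132 and 130 genes differed 1.5-fold, 2-fold and 4-fold between them. Among 22280 genes, the NPA comparison recovered 74.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 97.0% of those changed 4-fold, with 18 unchanged genes called. The iaa13 comparison recovered 85.1%, 91.0% and 100%, with 19 unchanged genes called, and the difference 70%, 88.6% and 97.7%, with 6. Far fewer genes were changed in this simulation than were called in the data, so these rates need not hold there. With no effect simulated, 0, 1 and 0 genes and 0, 1 and 1 of 49 lists were called with NPA, in iaa13 and in the difference. The simulated noise was drawn apart for each spot, so the genes of a list were not correlated. These list counts therefore cannot tell how often the preset correlation calls lists of correlated genes.

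Alternatives were a normexp offset of 10, no background correction, processed signals, median centring of each array, Aquantile between arrays, no filter and a stricter filter (above background in both dyes on all 6 arrays), the mean of a gene's probes, outlier spots kept, trended and robust variances, only the arrays of the comparison, the replicate number as a fixed or random block, stricter thresholds, and each array left out in turn. All NPA arrays lay on 1 slide and all iaa13 arrays on another, so a fit with the slide as a block could not be made. For the counts of genes called in both comparisons, some of these alternatives had not been planned. Ranges, highest and lowest values of adjusted p over the alternatives leave out camera with the correlation estimated. Its values, which were higher for every list called, are given apart. Settings added after the data were seen left out both replicate 3 arrays, or left out probes that carry a TG repeat of at least 6 units or a sequence shared by several loci (268 sequences, standing for up to 50 loci).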

Results

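The arrays measured transcripts in adventitious roots of rice, in the part of the root lying 15 to 25 mm behind the tip. Plants were untreated wild type (cultivar Taichung 65), wild type given 0.5 µM NPA for 48 h, and the untreated iaa13 mutant, which has the same background. NPA (N-1-naphthylphthalamic acid) blocks the movement of auxin between cells, and IAA13 is an AUX/IAA protein, one of the repressors of auxin-responsive genes. There were 3 arrays of NPA-treated over untreated wild type and 3 arrays of iaa13 over untreated wild type, each from 1 biological replicate. Every ratio here is log2 of the treated or mutant root (Cy3 dye) over untreated wild type (Cy5 dye), so a value above 0 means more signal in the treated or mutant root. The deposited table of values runs the opposite way. On the 6 arrays, between 68.5% and 74.1% of the spots that were not controls lay well above background in Cy3 and between 76.9% and 78.5% in Cy5, and 0 spots were saturated. The number of arrays limits the precision of all values. Ratios of single genes are given as mean ± SD (n = 3 arrays), differences between the comparisons with their standard error (SE), and p-values are limma's after Benjamini-Hochberg adjustment over 22280 genes.

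Across genes, which are not independent replicates, the ratios of pairs of NPA arrays correlated at r from 0.879 to 0.925, those of pairs of iaa13 arrays at 0.775 to 0.921, and those of an NPA and an iaa13 array at 0.278 to 0.530.

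The transcript of IAA13 itself (Os03g0742900) was lower in the mutant on all 3 arrays, with log2 ratios of -0.33, -0.50 and -0.34, a mean of -0.39 ± 0.10 and an adjusted p of 0.00494. All 4 probes of the gene gave means below 0 in the mutant, from -0.47 to -0.26. With NPA its ratios were 0.30, -0.01 and 0.17, a mean of 0.15 ± 0.16 that did not pass the threshold (adjusted p = 0.0991; over 13 alternative settings it ranged from 0.00552 to 0.410). That value passed with the replicate number as a block (adjusted p = 0.0208), with the mean of the probes (0.19, adjusted p = 0.0398) and without NPA replicate 2 (0.24, adjusted p = 0.0410), and it turned to -0.31 when arrays were centred on their median instead of being fitted by loess (adjusted p = 0.00552). The difference between the comparisons, iaa13 minus NPA, was -0.55 ± 0.10 SE (adjusted p = 0.00865). The labels do not say what the mutation changes, so this transcript does not check the sample labels.

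The first comparison asked which transcripts change when auxin transport is blocked. NPA lowered genes for core histones and DNA replication and genes for cytosolic ribosomal proteins, with 40 of 46 and 140 of 149 members lower. It also lowered 14 of 26 expansin genes. AUX/IAA repressors went the other way, with 14 of 25 higher, and so did cytochrome P450s, UDP-glycosyltransferases and WRKY transcription factors, of which 69 of 141, 35 of 78 and 32 of 58 rose. These lists passed camera with the preset correlation, but none passed with the correlation estimated (adjusted p = 0.639 with an estimated correlation for each). Among genes with a description, aldolase C-1 had the largest rise, and a glycine-rich protein gene had the largest fall not given as a bound.

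Aldolase C-1 (Os08g0120600) rose by 7.72 ± 0.19 with NPA (adjusted p = 6.28e-05), and a second enzyme of sugar phosphate metabolism, annotated as similar to pyrophosphate-fructose-6-phosphate 1-phosphotransferase (Os05g0194900), rose by 5.70 ± 0.32 (adjusted p = 1.51e-05). A terpene synthase-like gene (Os04g0340300) rose by 5.63 ± 0.51, and a disease resistance protein family gene (Os06g0279900) by 4.45 ± 0.19 (adjusted p = 2.30e-05 and 1.25e-05). The other large rises were those of an ABA response element binding factor (Os01g0859300, 3.92 ± 0.21), a mannose-binding lectin domain gene (Os10g0155100, 3.77 ± 0.59), a disease resistance response protein gene (Os03g0280700, 3.74 ± 0.03) and asparagine synthetase (Os03g0291500, 3.71 ± 0.69), with adjusted p between 2.77e-06 and 0.000449. Each of these 8 genes was higher on all 3 NPA arrays.

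The glycine-rich protein gene Os10g0452500 fell to -5.86 ± 0.23 with NPA (adjusted p = 1.25e-05). BCH2 (Os02g0112100) was at least 28.6-fold lower (adjusted p = 0.000229), a bound because its treated signal was not well above background on the NPA arrays. Genes for a glyoxal oxidase (Os03g0258900, -4.72 ± 0.67), a cupredoxin (Os06g0216700, -4.70 ± 0.63), a peroxidase (Os03g0369000, -4.55 ± 0.30), floral organ regulator 1 (Os07g0568700, -4.47 ± 0.18), an acid phosphatase (Os01g0191200, -4.46 ± 0.83) and a physical impedance induced protein (Os03g0103200, -4.46 ± 0.58) also fell, with adjusted p between 1.29e-05 and 0.000237. Each was lower on all 3 NPA arrays.

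In all, 14250 of 22280 genes passed the threshold with NPA, 6768 higher and 7482 lower, and 2105 of them by at least 2-fold, 870 higher and 1235 lower. When the arrays were centred on their median instead of fitted by loess, the median of all genes moved to -0.19, and 4882 genes were higher against 11182 lower. Without either array of replicate 3, a setting added after the data were seen, the count was 12894. Untreated wild type was in Cy5 on every array, so a dye effect of a probe is part of each NPA ratio and of each iaa13 ratio.

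Among the gene lists fixed beforehand, 10 of 32 passed the camera test with NPA, which compares a list with all other genes. 7 of them went up. AUX/IAA repressors rose (14 genes rose, 5 fell and 6 did not pass; adjusted p = 0.0271), led by IAA17 (Os03g0633500, 1.14 ± 0.06) and the AUX/IAA family genes Os01g0178500 (0.82 ± 0.03) and Os07g0182400 (2.26 ± 0.32). In the list of lignin and secondary wall synthesis, 20 rose, 6 fell and 15 did not pass (adjusted p = 0.0171); a phenylalanine ammonia-lyase gene (Os02g0627100) rose by 1.65 ± 0.12, while a cinnamoyl-CoA reductase gene (Os01g0283600) was at least 2.04-fold lower. In the jasmonate list, 10 rose, 2 fell and 3 did not pass (adjusted p = 0.0271), with the lipoxygenase genes Os02g0753300 at 0.67 ± 0.09 (0.07 and not passing with median centring, adjusted p = 0.326) and Os03g0700700 at 1.32 ± 0.11. Of the WRKY genes, 32 rose, 9 fell and 17 did not pass (adjusted p = 0.00496), with Os11g0116900 at 1.13 ± 0.09 and WRKY29 (Os07g0111400) at 1.46 ± 0.17. Of the UDP-glycosyltransferases, 35 rose, 14 fell and 29 did not pass (adjusted p = 0.0171), among them Os05g0552700 (1.89 ± 0.35) and Os04g0324100 (1.47 ± 0.17). Of the cytochrome P450s, 69 rose, 25 fell and 47 did not pass (adjusted p = 0.00380), among them Os01g0804400 (2.07 ± 0.19) and Os02g0504000 (1.82 ± 0.18). Of the shoot and photosynthesis markers, 14 rose, 5 fell and 8 did not pass (adjusted p = 0.0271), with genes for photosystem I subunits V (Os09g0481200, 0.58 ± 0.08) and II (Os08g0560900, 1.99 ± 0.56) higher. None of these lists passed when the correlation between genes was estimated (adjusted p = 0.639 with an estimated correlation for each).

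The 3 lists that went down with NPA were histones and DNA replication, cytosolic ribosomal proteins and expansins. In the first, 0 rose, 40 fell and 6 did not pass, with a median log2 ratio of -1.30 (adjusted p = 5.78e-11). Histone H4 (Os09g0433600) stood at -1.73 ± 0.19 and histone H2B (Os01g0839500) at -1.35 ± 0.16. In the second, 1 rose, 140 fell and 8 did not pass, with a median of -0.87 (adjusted p = 3.06e-20), for example L30 (Os01g0812800, -1.35 ± 0.09) and L31 (Os06g0319700, -1.58 ± 0.16). Of the expansins, 3 rose, 14 fell and 9 did not pass (adjusted p = 0.0335), and the beta-expansin genes Os03g0102700 and Os10g0555600 stood at -4.17 ± 0.26 and -2.27 ± 0.14. These lists did not pass either when the correlation was estimated (adjusted p = 0.639 with an estimated correlation). The expansin call was also lost with the replicate block (adjusted p = 0.0581), without NPA replicate 2 (adjusted p = 0.0535), with a stricter filter (adjusted p = 0.0569) and with median centring (adjusted p = 0.141), and ranged from 0.0203 to 0.141 over 12 alternatives. Median centring ended the calls of the AUX/IAA (adjusted p = 0.0641), lignin (adjusted p = 0.146) and jasmonate lists (adjusted p = 0.299) as well, each the highest of 12 alternatives, whose lowest were 0.00387, 0.00538 and 0.0241. The photosynthesis call was lost with the processed signals of the scanner software (adjusted p = 0.0571), with the stricter filter (adjusted p = 0.146) and without the replicate 3 arrays (adjusted p = 0.0595), with a lowest value of 1.56e-05.

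Of 17 lists written after the array's gene descriptions were read, 5 passed with NPA. Cyclins and kinesins fell (10 rose, 48 fell and 13 did not pass; adjusted p = 2.74e-05), for example the cyclin Os04g0563700 (-1.22 ± 0.05) and the kinesin Os01g0605500 (-1.16 ± 0.07). Replication machinery fell (1 rose, 12 fell and 2 did not pass; adjusted p = 0.00244), with MCM2 family gene Os11g0484300 at -1.81 ± 0.23 and MCM family gene Os05g0235800 at -1.45 ± 0.20. Response regulators rose (14 rose, 1 fell and 5 did not pass; adjusted p = 0.00694), with ARR11 (Os02g0796500) at 0.63 ± 0.09 and Os02g0557800 at 0.86 ± 0.07. Cellulose synthases rose (11 rose, 2 fell and 8 did not pass; adjusted p = 0.0130), led by Os07g0552800 (2.62 ± 0.19) and cellulose synthase-9 (Os10g0578200, 0.98 ± 0.16). Germin-like proteins rose (12 rose, 1 fell and 5 did not pass; adjusted p = 0.0130), although the member of smallest p, Os08g0189100, fell to -2.59 ± 0.11 and the next, Os03g0804500, rose by 1.56 ± 0.09. None of the 5 passed with the correlation estimated (adjusted p = 0.509 with an estimated correlation, 0.510 for the germin-like proteins). Median centring ended the calls of the response regulators (adjusted p = 0.138) and cellulose synthases (adjusted p = 0.422), whose lowest values over 12 alternatives were 0.00403 and 0.00427.

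Other auxin genes passed singly with NPA, in lists that did not pass. Of all genes, 64.0% passed with NPA, so counts near that share are no sign of a response particular to a list. This holds for the lists in the paragraphs that follow too. Of 14 auxin response factors, 6 rose and 3 fell, with ARF2 (Os06g0702600) at 2.05 ± 0.12 and ARF1 (Os04g0664400) at -2.78 ± 0.24. Of 10 GH3 genes, 5 rose and 2 fell, with Os05g0143800 at 0.49 ± 0.12 (0.11 with median centring, adjusted p = 0.194) and Os07g0592600 at -0.91 ± 0.31. Of 16 SAUR genes, 5 rose and 4 fell, and Os04g0608300 and Os04g0662200 stood at -1.35 ± 0.18 and -0.98 ± 0.17; the median of this list lay above 0 and its mean below. Of 8 auxin transport genes, 3 rose and 2 fell; the efflux carrier gene Os09g0554300 rose by 1.46 ± 0.29, and PIN2 (Os06g0660200) was at least 6.09-fold lower. Of 11 LOB domain genes, 1 rose and 5 fell, with LOB domain gene 12 (Os01g0825000) at least 2.52-fold lower and LOB domain gene 15 (Os05g0346800) at -1.02 ± 0.21. Camera's adjusted p for these lists lay between 0.305 and 0.963.

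Among further fixed lists that did not pass with NPA, 11 class III peroxidases rose and 17 of 33 fell, including Os07g0639400, which was at least 3.33-fold lower, and peroxidase P7 (Os02g0236600, -3.47 ± 0.48). Of 41 genes of ROS production and scavenging, 12 rose and 11 fell, and the metallothionein genes Os12g0571100 and Os12g0568500 stood at -1.42 ± 0.24 and -2.19 ± 0.40. Of 17 ethylene genes, 7 rose and 6 fell, with an ACC oxidase 1 gene (Os09g0451000) at 3.63 ± 0.23. Of 15 iron and metal uptake genes, 3 rose and 11 fell; the first by p was an aminotransferase gene (Os11g0644800, 2.13 ± 0.18), and iron-regulated transporter 1 (Os03g0667500) stood at -2.48 ± 0.44. Of 28 pectin-modifying enzymes, 10 rose and 11 fell (pectinesterase Os04g0553500, at least 10.2-fold lower). Of 9 genes matched as endoglucanases, 2 rose and 4 fell; the first was a barwin-related gene (Os02g0637000, -3.21 ± 0.25). Of 51 glutathione transferases, 20 rose and 20 fell (Os01g0374000, 2.37 ± 0.18). Of 77 defence proteins, 28 rose and 18 fell (thaumatin-like Os06g0691200, -2.23 ± 0.17). Of 122 heat shock proteins, 37 rose and 32 fell (DnaJ family Os04g0549600, 1.26 ± 0.06). Of 26 genes of abscisic acid and dehydration, 10 rose and 8 fell (LEA3 family Os01g0314800, 2.88 ± 0.30).

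Nutrient, water and hormone lists, which did not pass either, also held members in both directions with NPA. Of 17 nitrate and ammonium genes, 9 rose and 8 fell (ammonium transporter Os02g0550800, at least 1.96-fold lower), and the list's median of 0.40 and mean of -0.09 differed in sign. Of 21 genes of phosphate starvation, 6 rose and 8 fell (purple acid phosphatase Os12g0151000, at least 2.22-fold lower). Of 5 aquaporins, 2 rose and 3 fell (Os07g0448200, 1.20 ± 0.35), again with a median below 0 and a mean above. Of 14 genes matched as gibberellin, 2 rose and 8 fell, among them the gibberellin regulated family gene Os03g0760800 (-1.08 ± 0.19), but the list also holds genes of ribosomal protein L9. Of 9 root meristem transcription factors, 4 rose and 1 fell (scarecrow-like 9, Os11g0705800, 0.54 ± 0.09). Of 7 cytokinin genes, 1 rose and 1 fell (histidine-containing phosphotransfer gene Os09g0567400, -0.21 ± 0.02). Of 4 suberin markers, 2 rose. CYP86A1 (Os01g0854800) stood at 0.88 ± 0.91, a call lost without iaa13 replicate 1, 2 or 3 (adjusted p from 0.0622 to 0.0653; 0.0184 to 0.181 over 13 alternatives). The second suberin marker, Os10g0577900, rose by 0.11 ± 0.01, a call lost without any 1 of the 6 arrays (adjusted p from 0.0689 to 0.148), and turned to -0.22 with median centring. Fewer than 3 genes were measured for mitosis (2 fell, MAD2 Os04g0486500 to -0.74 ± 0.15), xyloglucan endotransglucosylases (1 of 2 rose, Os06g0697000, 2.21 ± 0.45) and root hair markers (0 of 2 passed). The phloem marker Os07g0186000 rose by 0.18 ± 0.08, did not pass without NPA replicate 2 (adjusted p = 0.0514) or NPA replicate 3 (0.0745), and turned to -0.35 with median centring (0.000889). No gene matched the lists of ERF factors by that name, xylem markers or Casparian strip markers.

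Of the added lists that did not pass with NPA, 34 haem peroxidases rose and 41 of 96 fell. Of 11 xyloglucan endotransglycosylases, 1 rose and 6 fell, and Os04g0631200 stood at -1.67 ± 0.20. Of 16 cellulases, 3 rose and 10 fell (Os01g0220100, -2.37 ± 0.34). Of 48 NAC factors, 10 rose and 20 fell (Os02g0810900, -2.59 ± 0.30). Of 15 extensins, 6 rose and 5 fell (Os01g0726100, at least 19.7-fold lower), with a median above 0 and a mean below. Of 61 AP2/ERF factors, 15 rose and 14 fell (ERF3, Os06g0604000, at least 5.08-fold lower), again with median and mean on either side of 0. Of 38 lipid transfer proteins, 8 rose and 12 fell (Os10g0552600, -1.40 ± 0.23), and of 13 major intrinsic proteins, 4 rose and 6 fell (Os04g0550800, at least 2.71-fold lower). Of 22 DUF588 (CASP-like) genes, 10 rose and 4 fell (Os05g0456500, 0.68 ± 0.12). Of 5 root cap genes, 2 rose and 3 fell (Os01g0968400, at least 1.86-fold lower). Of 11 genes of sucrose transport and callose, 2 rose and 6 fell (Os02g0576600, at least 1.44-fold lower), and of 10 fermentation and haemoglobin genes, 3 rose and 5 fell (pyruvate decarboxylase Os01g0160100, 0.96 ± 0.11).

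Adjusted over the list alone, the NPA counts of the fixed lists differed from those over all genes in 9 lists: 4 SAUR genes rose and 4 fell, 10 pectin-modifying enzymes rose and 12 fell, 12 ROS genes rose and 9 fell, 8 ethylene genes rose and 6 fell, 10 abscisic acid genes rose and 9 fell, 69 cytochrome P450s rose and 26 fell, 1 ribosomal protein gene rose and 141 fell, 0 suberin genes passed, and 15 photosynthesis markers rose and 5 fell.

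**Figure D1:**
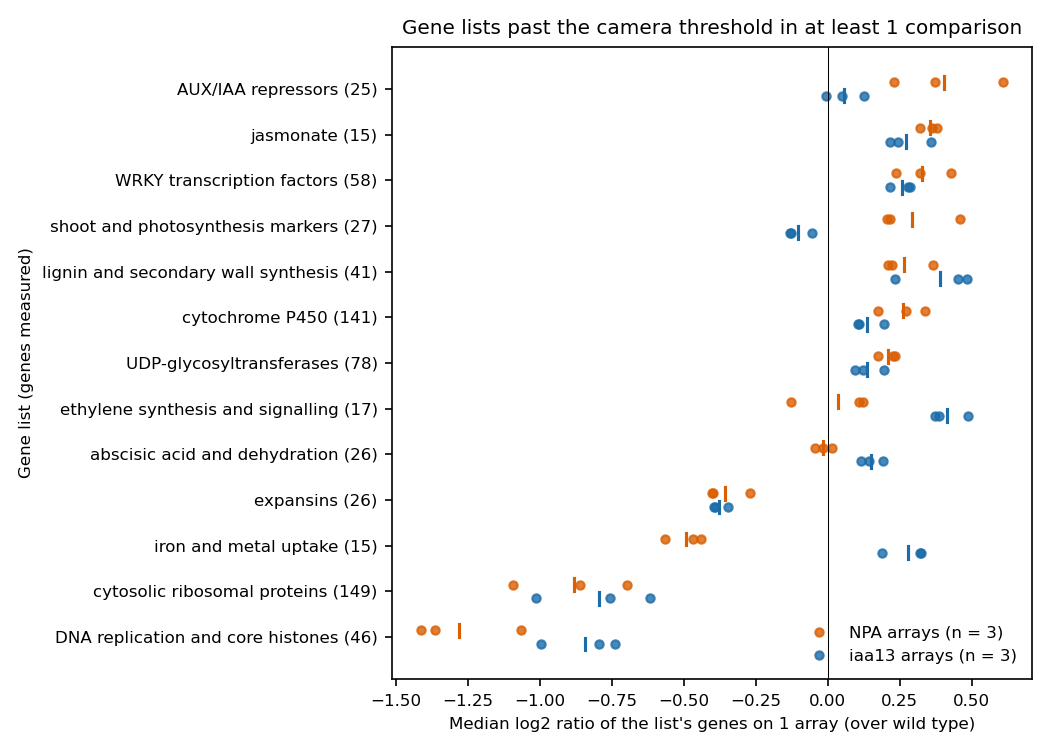
Median log2 ratio over untreated wild type of the genes of each list (vertical axis, number of genes measured in parentheses) on each of 3 NPA arrays (orange points) and 3 iaa13 arrays (blue points), with the mean of the 3 points as a bar. Shown are the fixed lists past the camera threshold with NPA or in iaa13; histones lay between -1.41 and -1.07 on the NPA arrays.

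The second comparison asked which transcripts differ in untreated roots of the iaa13 mutant. Histone and DNA replication genes and cytosolic ribosomal protein genes were lower here too, 41 of 46 and 142 of 149. Lignin and secondary wall genes (25 of 41), WRKY genes (32 of 58) and ethylene genes (9 of 17) were among those that rose in the mutant. These lists passed camera with the preset correlation, but none did with the correlation estimated (adjusted p from 0.424 to 0.506 with an estimated correlation). Among genes with a description whose ratio is not given as a bound, a bHLH gene, WRKY64 and an AP2 gene of the RAP2.6 type rose most. A thionin gene and a lipid transfer gene fell most among them.

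In iaa13, the bHLH gene Os04g0301500 rose by 5.81 ± 1.30 (adjusted p = 0.000555), WRKY64 (Os12g0116700) by 5.72 ± 0.42 (adjusted p = 0.000272) and the RAP2.6 gene Os08g0474000 by 5.38 ± 1.72 (adjusted p = 0.00106). A RING finger gene (Os02g0559800, 5.32 ± 1.25), a CBF-like gene (Os09g0522000, 4.75 ± 2.65), a ZIM domain gene (Os03g0180800, 4.42 ± 1.40), an F-box gene (Os09g0341600, 4.36 ± 1.02) and an amino acid transporter gene (Os01g0597600, 4.30 ± 1.64) also rose, with adjusted p between 0.000848 and 0.0118. The CBF-like gene did not pass without iaa13 replicate 1 (3.84, adjusted p = 0.0637) or without iaa13 replicate 2 (4.14, adjusted p = 0.0692), and its lowest adjusted p over 13 alternatives was 0.000678. All 8 were higher on the 3 mutant arrays, but replicate 3 gave smaller rises: the median over 145 genes risen at least 4-fold was 3.39, 2.80 and 1.85 on iaa13 arrays 1, 2 and 3.

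The largest falls in iaa13 not given as a bound were those of Cp-thionin (Os02g0629800, -3.64 ± 1.18, adjusted p = 0.00218) and a lipid transfer gene (Os10g0554800, -3.32 ± 1.74, adjusted p = 0.00847). Peroxidase 1 (Os07g0639000) was at least 6.49-fold lower (adjusted p = 0.0137) and the lipid transfer gene Os01g0914300 at least 7.66-fold lower (adjusted p = 0.0144). Neither of these passed without iaa13 replicate 1 (adjusted p = 0.0614 and 0.0737) or without iaa13 replicate 2 (adjusted p = 0.0787 and 0.0822), and their lowest values over 12 alternatives were 0.000584 and 0.000305. A phosphoethanolamine methyltransferase gene (Os05g0548900) fell to -2.93 ± 0.55 (adjusted p = 0.000979). The bHLH gene Os05g0103000 and a SNF1 kinase anchoring gene (Os07g0687300, -2.82) are measured by probes with a run of at least 6 TG units, and Os06g0262800, a senescence-associated gene, by a probe with a shorter run (-2.86 ± 0.67). Of 25 probes with a run of at least 6 units, 22 were lower in iaa13, so whether the first pair of values are changes of the genes is open. Probes with a longest run of 5 units had a median of only -0.24 in iaa13, and whether the run in the probe of Os06g0262800 contributes to its value was not tested.

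**Figure D2:**
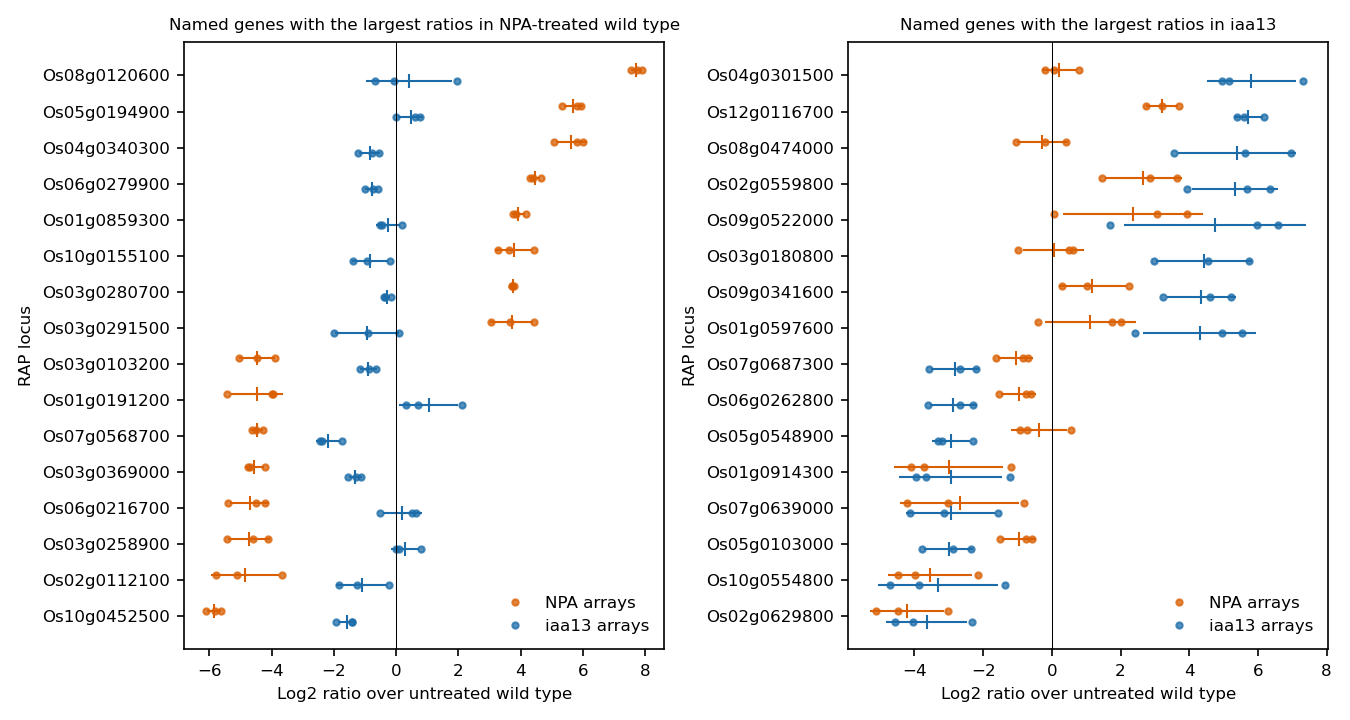
Log2 ratios over untreated wild type (horizontal axis) of the named genes with the largest rises and falls with NPA (left) and in iaa13 (right), with 1 point per array, the mean as a tick and 1 SD as a line. Aldolase C-1 (Os08g0120600) lay at 7.72 with NPA and at 0.41 in iaa13.

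In iaa13, 11866 of 22280 genes passed, 5387 higher and 6479 lower, and 1007 by at least 2-fold, 599 higher and 408 lower. The count fell to 7623 without iaa13 replicate 2, and it was 10727 without either array of replicate 3. With median centring the median of all genes moved to -0.17, and 4241 genes were higher against 10677 lower.

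In the mutant, 11 of 32 fixed lists passed the camera test, 8 of them up. For lignin and secondary wall synthesis, 25 rose, 2 fell and 14 did not pass (adjusted p = 4.68e-05), led by a 4-coumarate CoA ligase gene (Os08g0448000, 1.71 ± 0.10) and the phenylalanine ammonia-lyase gene Os05g0427400 (1.81 ± 0.17). Of the WRKY genes, 32 rose, 5 fell and 21 did not pass (adjusted p = 7.18e-05), among them WRKY64 and a WRKY10 gene (Os05g0537100, 1.87 ± 0.47). Ethylene genes rose (9 rose, 1 fell and 7 did not pass; adjusted p = 0.00492), with the ACC oxidase 1 gene Os09g0451000 at 1.90 ± 0.16 and an ethylene insensitive 3 family gene (Os07g0685700) at 1.16 ± 0.39. In the jasmonate list, 9 rose, 1 fell and 5 did not pass (adjusted p = 0.0189), with lipoxygenase Os04g0447100 at 2.52 ± 0.41 and allene oxide cyclase (Os03g0438100) at 0.74 ± 0.09. For abscisic acid and dehydration, 11 rose, 2 fell and 13 did not pass (adjusted p = 0.0318), with LEA3 gene Os01g0314800 at 2.39 ± 0.28 and Os02g0543000 at 0.91 ± 0.11. For iron and metal uptake, 5 rose, 0 fell and 10 did not pass (adjusted p = 0.0223), with the metal transporter gene Os01g0503400 at 0.48 ± 0.10 (0.18 and not passing with the mean of its probes, adjusted p = 0.112) and the aminotransferase gene Os11g0644800 at 0.40 ± 0.08. Of the UDP-glycosyltransferases, 24 rose, 10 fell and 44 did not pass (adjusted p = 0.0189), with Os04g0523600 at 1.41 ± 0.25 and Os07g0503900 at -1.21 ± 0.19. Of the cytochrome P450s, 52 rose, 18 fell and 71 did not pass (adjusted p = 0.0150); the first by p was a P450 reductase gene (Os08g0243500, 0.75 ± 0.05) and the next Os12g0150200 (3.74 ± 0.77). None of these passed with the correlation estimated (adjusted p = 0.424 with an estimated correlation for the lignin, jasmonate and WRKY lists, 0.506 for the others).

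Histones and DNA replication (0 rose, 41 fell and 5 did not pass; median -0.83; adjusted p = 9.49e-11) and cytosolic ribosomal proteins (1 rose, 142 fell and 6 did not pass; median -0.81; adjusted p = 1.20e-23) went down in iaa13. Histone H4 (Os09g0433600) stood at -1.16 ± 0.15, histone H2B (Os01g0839500) at -0.99 ± 0.13, S19-3 (Os03g0424800) at -0.83 ± 0.02 and S7 (Os02g0324500) at -0.83 ± 0.01. Expansins went down (4 rose, 14 fell and 8 did not pass; adjusted p = 0.0318), with beta-expansin 3 (Os04g0530100) at -0.85 ± 0.12 and Os03g0645000 at -1.36 ± 0.19. With the correlation estimated these lists did not pass (adjusted p = 0.506 with an estimated correlation, 0.424 for expansins). Leaving out single arrays ended the calls of expansins (without iaa13 replicate 3, adjusted p = 0.0557), abscisic acid genes (without iaa13 replicate 1, adjusted p = 0.0548), iron genes and UDP-glycosyltransferases (without iaa13 replicate 2, adjusted p = 0.0501 for each). Median centring ended those of expansins (adjusted p = 0.157), ethylene (0.0753), abscisic acid (0.0573), jasmonate (0.0536) and iron (0.379), each the highest of 12 alternatives, and processed signals that of expansins (0.0540). The lowest values over the alternatives were 0.00267 for expansins and abscisic acid, 0.00131 for ethylene, 0.00975 for jasmonate, 0.00546 for iron and 0.00439 for UDP-glycosyltransferases.

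Of the added lists, 6 passed in iaa13. Cyclins and kinesins fell (8 rose, 46 fell and 17 did not pass; adjusted p = 0.000987), with the cyclin Os04g0563700 at -0.81 ± 0.09 but the cyclin domain gene Os10g0563900 at 1.07 ± 0.08. Replication machinery fell (3 rose, 10 fell and 2 did not pass; adjusted p = 0.0335), with replication factor C genes Os04g0569000 and Os02g0775200 at -0.77 ± 0.03 and -0.63 ± 0.03. AP2/ERF factors rose (25 rose, 13 fell and 23 did not pass; adjusted p = 0.0415), although the first by p, Os01g0657400 and Os06g0604000, fell to -1.08 ± 0.16 and -1.64 ± 0.36, and Os02g0764700 rose by 4.21 ± 1.17. Response regulators rose (12 rose, 0 fell and 8 did not pass; adjusted p = 0.00387), with Os10g0362300 at 0.51 ± 0.11. NAC factors rose (18 rose, 7 fell and 23 did not pass; adjusted p = 0.0415), with Os01g0261200 at 0.60 ± 0.05 and Os02g0252200 at -1.30 ± 0.18. Cellulose synthases rose (9 rose, 2 fell and 10 did not pass; adjusted p = 0.0415), with CesA-2 (Os01g0750300) at 0.52 ± 0.05 and Os09g0422500 at 0.48 ± 0.06. None passed with the correlation estimated (adjusted p = 0.561 with an estimated correlation, 0.655 for AP2/ERF factors and 0.686 for cellulose synthases). The NAC call was lost with the replicate block (adjusted p = 0.0668), with the stricter filter (0.0598) and without NPA replicate 1 (0.0555) or iaa13 replicate 2 (0.0676). The cellulose synthase call was lost without NPA replicate 3 (0.0552), without iaa13 replicate 2 (0.0676), without both replicate 3 arrays (0.0604) and with median centring (0.285). Median centring also ended the calls of replication machinery (0.0811) and response regulators (0.272), the loss of the replicate 3 arrays that of replication machinery (0.0604), and the stricter filter that of AP2/ERF factors (0.0707). The lowest values over 12 alternatives were 0.0273 for NAC factors and cellulose synthases, 0.0160 for replication machinery, 0.00134 for response regulators and 0.00982 for AP2/ERF factors.

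AUX/IAA repressors did not pass as a list in iaa13 (8 rose, 4 fell and 13 did not pass; adjusted p = 0.420); Os05g0178600 rose by 0.52 ± 0.09 and IAA18 (Os02g0228900) fell to -0.98 ± 0.17. Of the auxin response factors, 2 rose and 6 fell, with ARF1 (Os04g0664400) at -1.84 ± 0.25 and ARF7 (Os02g0141100) at 0.42 ± 0.14. Of the GH3 genes, 3 rose and 3 fell (Os05g0500900, -0.83 ± 0.06; Os01g0785400, at least 1.83-fold lower). SAUR genes held 3 that rose and 5 that fell (Os04g0662200, -0.80 ± 0.08; Os04g0608300, -0.78 ± 0.18), with a median above 0 and a mean below. Auxin transport genes held 1 that rose and 4 that fell, with the efflux carrier gene Os01g0715600 at -1.31 ± 0.07 and PIN2 (Os06g0660200) at -1.43 ± 0.40. LOB domain genes held 4 in each direction (LOB domain gene 6, Os03g0659700, -0.54 ± 0.01; gene 12, Os01g0825000, -0.56 ± 0.05), with a median above 0 and a mean below. ROS genes held 8 that rose and 11 that fell, with ascorbate peroxidase (Os03g0285700) at -0.43 ± 0.10 and metallothionein Os05g0111300 at -1.98 ± 0.46. Of the shoot and photosynthesis markers, 3 rose and 5 fell, and the list's median relative to all genes, -0.06, turned to 0.31 with median centring (adjusted p = 0.00479; 0.00479 to 0.928 over 12 alternatives). The largest fall in this list, that of Os03g0592500, was measured by a probe with a TG repeat.

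Of all genes, 53.3% passed in iaa13, and the counts of lists that did not pass are to be read against that share. Further lists that did not pass in iaa13 are given as counts of genes that rose and fell. These were 6 and 12 class III peroxidases, 6 and 11 pectin-modifying enzymes, 25 and 17 defence proteins, 14 and 11 glutathione transferases, 20 and 39 heat shock proteins, 3 and 3 nitrate and ammonium genes, 8 and 1 phosphate genes, 5 and 6 gibberellin genes, and 4 and 1 root meristem factors. Among the smaller lists these were 1 and 0 aquaporins, 1 and 0 cytokinin genes, 0 and 1 endoglucanases and 1 and 0 suberin markers. Among the added lists they were 31 and 32 haem peroxidases, 5 and 7 cellulases, 8 and 14 lipid transfer proteins, 8 and 0 germin-like proteins, 3 and 8 extensins, 9 and 3 DUF588 genes, 2 and 3 xyloglucan endotransglycosylases, 3 and 2 major intrinsic proteins, 0 and 4 root cap genes, 4 and 3 genes of sucrose transport and callose, and 3 and 2 fermentation genes. The cellulase Os07g0440100 was at least 6.41-fold higher and peroxidase Os07g0639400 stood at -1.09 ± 0.08.

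Adjusted over the list alone, the iaa13 counts of the fixed lists differed in 11 lists: 4 LOB domain genes rose and 5 fell, 4 expansins rose and 15 fell, 1 xyloglucan endotransglucosylase rose and 1 fell, 26 lignin genes rose and 2 fell, 33 WRKY genes rose and 5 fell, 4 iron genes rose and 0 fell, 23 UDP-glycosyltransferases rose and 8 fell, 49 cytochrome P450s rose and 18 fell, 19 heat shock genes rose and 38 fell, 2 ribosomal protein genes rose and 143 fell, and 2 photosynthesis markers rose and 3 fell.

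The third comparison asked where the effects of NPA and of the mutation differ, as iaa13 minus NPA. The ratio was higher in iaa13 than with NPA for 26 of 46 histone and DNA replication genes, 11 of 15 iron uptake genes and, among added lists, 31 of 71 cyclins and kinesins, 8 of 15 replication genes and 21 of 48 NAC factors. It was lower for 13 of 27 photosynthesis markers and higher for 2. These lists passed camera with the preset correlation, but none passed with the correlation estimated (adjusted p from 0.356 to 0.895 with an estimated correlation). Aldolase C-1, which rose with NPA, was among the genes with large negative differences, and the bHLH gene Os04g0301500, which rose in iaa13, was among those with large positive ones.

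The differences were 5.66 ± 0.86 SE for the RAP2.6 gene Os08g0474000, 5.59 ± 0.64 SE for Os04g0301500, 5.51 ± 0.58 SE for the acid phosphatase gene Os01g0191200, 5.01 ± 0.37 SE for the glyoxal oxidase gene Os03g0258900 and 4.90 ± 0.41 SE for the cupredoxin gene Os06g0216700, with adjusted p between 0.000509 and 0.00466. On the negative side they were -7.31 ± 0.64 SE for aldolase C-1, -6.48 ± 0.29 SE for Os04g0340300, -5.23 ± 0.24 SE for Os05g0194900, -5.23 ± 0.14 SE for Os06g0279900 and -4.65 ± 0.58 SE for asparagine synthetase (Os03g0291500), with adjusted p between 4.81e-05 and 0.00238. For Os08g0474000 the NPA-treated signal, and for Os04g0340300 and Os06g0279900 the mutant signal, was not well above background, so the size of these differences is uncertain.

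The difference passed for 8027 of 22280 genes, 4088 higher in iaa13 and 3939 lower, and for 1501 by at least 2-fold, 812 higher and 689 lower. The count was 5295 without iaa13 replicate 1, 5257 without iaa13 replicate 2 and 5676 without either array of replicate 3. With a random replicate number it rose to 12302. All NPA arrays were on 1 slide and all iaa13 arrays on another, so slide and group cannot be told apart; a dye effect equal on all arrays cancels in this difference.

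In the histone list, 26 genes were higher in iaa13 than with NPA and 2 lower (median 0.44, adjusted p = 0.000500), for example H2A (Os03g0743400, 1.08 ± 0.12 SE) and H2B (Os01g0502900, 0.37 ± 0.06 SE). In the iron list, 11 were higher and 2 lower (median 0.73, adjusted p = 0.0232), with iron-regulated transporter 1 (Os03g0667500) at 2.89 ± 0.23 SE. Of the photosynthesis markers, 2 were higher and 13 lower (median -0.25, adjusted p = 0.0308), with photosystem I subunit V (Os09g0481200) at -0.75 ± 0.07 SE. These 3 of 32 fixed lists did not pass with the correlation estimated (adjusted p = 0.895 with an estimated correlation for each). The photosynthesis call was lost with the replicate block (adjusted p = 0.0698), with processed signals (0.0879), with the stricter filter (0.361), without NPA replicate 3 (0.0643), without iaa13 replicate 3 (0.0717) and without both (0.142), and ranged from 0.00726 to 0.361 over 12 alternatives. Cyclins and kinesins (31 higher and 5 lower, adjusted p = 0.00294), replication machinery (8 and 0, adjusted p = 0.00529) and NAC factors (21 and 2, adjusted p = 0.00529) were the 3 of 17 added lists that passed, all higher in iaa13. They did not pass with the correlation estimated (adjusted p = 0.356 with an estimated correlation for NAC factors and 0.700 for the others). A kinesin gene (Os12g0616000, 0.84 ± 0.10 SE), a ribonucleotide reductase gene (Os06g0168600, 0.82 ± 0.11 SE) and the NAC gene Os02g0555300 (1.83 ± 0.11 SE) were examples.

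AUX/IAA repressors did not pass as a list in the difference (3 higher and 12 lower in iaa13, adjusted p = 0.116), but did with the stricter filter (adjusted p = 0.0116; 0.0116 to 0.203 over 12 alternatives). IAA17 (Os03g0633500) differed by -1.49 ± 0.07 SE and Os05g0523300 by 1.91 ± 0.19 SE. ARF2 (Os06g0702600) differed by -1.95 ± 0.08 SE and the efflux carrier gene Os01g0715600 by -1.03 ± 0.11 SE. PIN2 (Os06g0660200) and LOB domain gene 12 (Os01g0825000) had higher ratios in iaa13, by a size that was not measured because their NPA-treated signal was not well above background. Ribosomal proteins did not pass as a list (12 higher and 1 lower, adjusted p = 0.299), but did without NPA replicate 1 (adjusted p = 0.0124), without iaa13 replicate 2 (0.00280) and with median centring (0.0322), and ranged from 0.00280 to 0.992 over 12 alternatives. For all genes, the share past the threshold for the difference was 36.0%. Some of the other fixed lists are given as counts of genes higher and lower in iaa13 than with NPA. These were 1 and 5 auxin response factors, 0 and 2 GH3 genes, 2 and 2 SAUR genes and 1 and 3 auxin transport genes. They were 4 and 1 LOB domain genes, 8 and 8 ROS genes, 14 and 7 lignin genes and 15 and 10 WRKY genes. UDP-glycosyltransferases held 11 and 24, and cytochrome P450s 25 and 45. No test of these lists passed the threshold. Adjusted over the list alone, 28 histone genes were higher and 2 lower, 2 ribosomal protein genes were higher and 0 lower, and the counts of the iron, photosynthesis and AUX/IAA lists did not change.

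The fourth comparison set the genes called in both against each other. WRKY64 (Os12g0116700) rose with NPA (3.21 ± 0.48) and in iaa13 (5.72 ± 0.42), and so did a RING finger gene (Os02g0559800, 2.66 ± 1.12 and 5.32 ± 1.25), a WRKY10 gene (Os01g0186000, 2.80 ± 0.81 and 2.58 ± 0.55), a harpin-induced domain gene (Os01g0864500, 2.43 ± 0.61 and 2.63 ± 1.11) and LEA3 gene Os01g0314800 (2.88 ± 0.30 and 2.39 ± 0.28). Cp-thionin (Os02g0629800) was at least 15.3-fold lower with NPA and stood at -3.64 ± 1.18 in iaa13. The lipid transfer gene Os10g0554800 was at least 10.3-fold lower with NPA and stood at -3.32 ± 1.74 in iaa13. The lipid transfer gene Os01g0914300 was at least 7.39-fold lower with NPA and at least 7.66-fold lower in iaa13, and peroxidase 1 (Os07g0639000) at least 5.71-fold and at least 6.49-fold lower. Both lost their NPA calls without NPA replicate 1 (adjusted p = 0.0554 and 0.0673) or NPA replicate 2 (0.0595 and 0.0784), and their iaa13 calls without iaa13 replicate 1 (0.0737 and 0.0614) or iaa13 replicate 2 (0.0822 and 0.0787). These are the highest values over 12 alternatives, and the lowest with NPA were 5.45e-05 and 0.000197. An Ole e 1 and extensin domain gene (Os05g0531200) stood at -2.79 ± 0.63 and -2.40 ± 0.38.

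Opposite directions were seen for phi-1 (Os02g0756200, -1.60 ± 0.52 with NPA and 2.53 ± 0.37 in iaa13), a peroxidase (Os10g0109300, 2.97 ± 0.30 and -1.54 ± 0.26), a cytochrome P450 (Os10g0440000, -2.51 ± 0.41 and 1.41 ± 0.43) and a C2H2 zinc finger gene (Os01g0838600, -1.48 ± 0.54 and 1.38 ± 0.43). The glycine-rich protein gene Os06g0317200 was at least 3.39-fold lower with NPA and stood at 1.45 ± 0.60 in iaa13, a call lost without iaa13 replicate 2 (1.18, adjusted p = 0.0581; 0.000552 to 0.0581 over 12 alternatives). Differences between the comparisons passed for all 5 of these genes, with adjusted p between 0.000103 and 0.00298, though the size for Os06g0317200 is uncertain because its NPA-treated signal was not well above background.

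Both comparisons called 2882 genes higher, where independent lists would share 1636, and 4379 lower, where independent lists would share 2176. They called 1333 in opposite directions, against 3777 for independent lists, and this count was 2219 with the replicate number as a block. At 2-fold or more, 192 genes were higher in both, 277 lower in both and 27 opposite, against 23.4, 22.6 and 49.1. Without iaa13 replicate 2 the counts were 1795 higher in both and 680 opposite, and without iaa13 replicate 1 the opposite count was 786. Without either array of replicate 3 the 3 counts were 2540, 3977 and 1121. With median centring they were 2655, 8383 and 1002.

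Across genes, the ratios of the 2 comparisons correlated at r = 0.468 with a covariance of 0.153, and 69.4% of genes had the same sign. In 20 simulations of unchanged groups against shared wild-type RNA, r averaged 0.557 (0.542 to 0.581) and the covariance averaged 0.00648. In them 68.9% of genes had the same sign (68.4% to 69.5%). The observed r and share of equal signs did not exceed the simulated ones. The simulated r follows from the correlation of 0.559 between same-numbered arrays that was put in. The share of equal signs ignores the size of the ratios, and r is unchanged when all ratios are scaled alike. Neither can therefore decide whether the overlap goes beyond shared wild-type RNA. The simulated groups were unchanged, so 0 simulated genes were called in both, which says nothing about the 7261 genes called in the same direction. The observed covariance exceeded the simulated one by 0.146. With 3 wild-type replicates the controls could not be split into parts of at least 2. A dye effect of a probe is also part of both ratios, because no array has the dyes swapped. It was not in the simulation or in the counts for independent lists, and part of the excess may come from it. A gene's other probe is a further measurement of its transcript. Over 3182 genes with a second probe, the covariance of the NPA ratio of 1 probe with the iaa13 ratio of the other was 0.0975. Over the same 3182 genes, the covariance of both ratios taken from the same probe was 0.117. The value of 0.0975 is to be set against 0.117 and not against 0.153, which is over all genes.

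**Figure D3:**
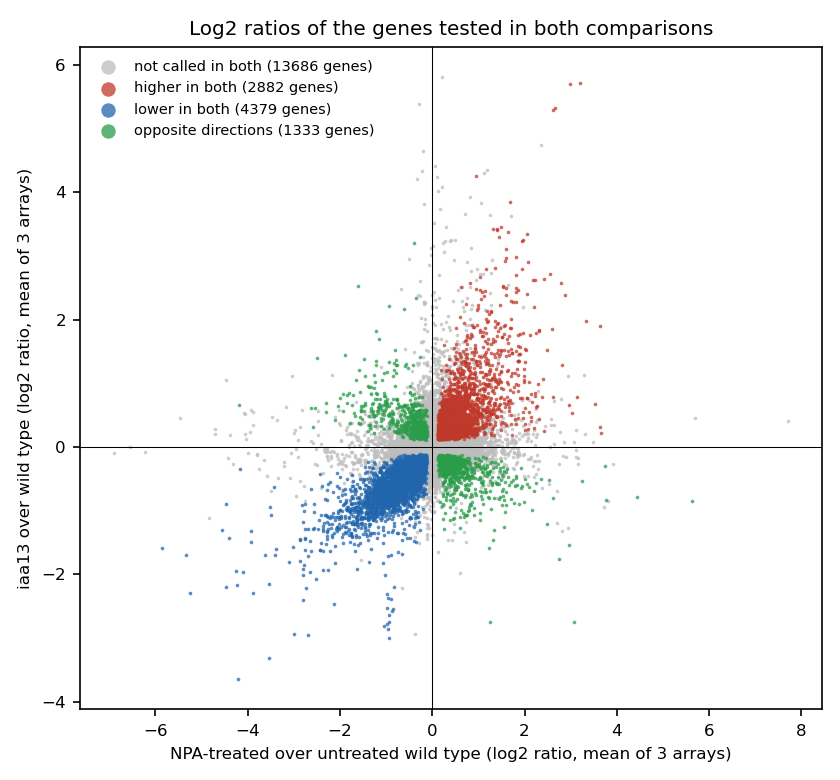
Log2 ratio with NPA (horizontal axis) against log2 ratio in iaa13 (vertical axis), each the mean of 3 arrays, for 22280 genes, coloured by the calls in both comparisons. 2882 genes lie at upper right (red), 4379 at lower left (blue) and 1333 at upper left and lower right (green).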

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

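Of the tests weighed here, those of an equal dye effect on the histone list, of shared wild-type deviations, of fewer dividing cells, and both tests of the TG repeat were chosen only after the result was seen; the others were chosen before.

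The effects of NPA and of the mutation were compared with each other by limma's test of the difference, and that test passed for 8027 genes. It also passed, through camera, for 6 gene lists: the median differences, iaa13 minus NPA, were 0.44 for histones and DNA replication, 0.73 for iron and metal uptake, -0.25 for shoot and photosynthesis markers, 0.25 for cyclins and kinesins, 0.40 for replication machinery and 0.20 for NAC factors. None of these 6 list calls passed with the correlation estimated (adjusted p = 0.895 with an estimated correlation for the histone, iron and photosynthesis lists, 0.700 for cyclins and replication machinery and 0.356 for NAC factors). The photosynthesis call was also lost with the replicate block (adjusted p = 0.0698; 0.00726 to 0.361 over 12 alternatives). IAA13 itself (Os03g0742900) differed by -0.55.

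Among the genes with the largest fitted positive differences were the RAP2.6 gene Os08g0474000 (5.66), the bHLH gene Os04g0301500 (5.59), the acid phosphatase gene Os01g0191200 (5.51), the glyoxal oxidase gene Os03g0258900 (5.01) and the cupredoxin gene Os06g0216700 (4.90). Among those with the largest negative ones were aldolase C-1 (Os08g0120600, -7.31), the terpene synthase-like gene Os04g0340300 (-6.48), the phosphotransferase gene Os05g0194900 (-5.23), the disease resistance gene Os06g0279900 (-5.23) and asparagine synthetase (Os03g0291500, -4.65). Among genes called in opposite directions, phi-1 (Os02g0756200) differed by 4.13, peroxidase Os10g0109300 by -4.51, the glycine-rich protein gene Os06g0317200 by 3.33, the cytochrome P450 Os10g0440000 by 3.91 and the C2H2 zinc finger gene Os01g0838600 by 2.86. The sizes for Os08g0474000 and Os06g0317200 (NPA-treated signal) and for Os04g0340300 and Os06g0279900 (mutant signal) are uncertain, because those signals were not well above background.

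Probes for microRNA precursors and mature microRNAs, which no gene comparison uses, also gave a signal. Of 510 probes, 109 were above background and tested. With NPA 35 of these were higher and 17 lower, and in iaa13 5 were higher and 2 lower. Whether the signal came from mature microRNAs or from longer precursor transcripts was not tested.

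The first pattern is the fall of cytosolic ribosomal protein genes (medians -0.87 with NPA and -0.81 in iaa13) and of histone genes (-1.30 and -0.83) in both comparisons. The lowest median of 10000 random probe lists matched on intensity and base content was -0.161 with NPA and -0.109 in iaa13, so the ribosomal list lay at least 0.699 below it, which argues against an intensity or base content effect of the dyes. Histone genes differed between the comparisons by a median of 0.441, with 26 of 46 higher in iaa13 and 2 lower. Camera's adjusted p for this difference was 0.0005, or 0.895 with an estimated correlation, and fry's p was 0.0554. Against wild type, fry's unadjusted p for histones was 0.000351 with NPA and 0.00183 in iaa13. For ribosomal proteins it was 0.00104 and 0.00169. Camera with the preset correlation and the 26 single genes argue against an equal dye effect on the histone list as the whole cause only. Camera with the correlation estimated and fry did not pass for this difference and do not add to that. A dye effect that differed between the slides cannot be told apart from the groups. Over 3182 genes, chance deviations shared through wild type gave 7.11% of the covariance between different probes of a gene. This share was not computed for the ribosomal or histone lists alone, so it does not settle their fall. Fewer dividing cells could lower histone genes, and cyclins and kinesins fell in both comparisons as this needs (median nearer to 0, -0.309; larger adjusted p = 0.000987), though not past the threshold with the correlation estimated (adjusted p = 0.509 with NPA and 0.561 in iaa13 with an estimated correlation). A dye effect specific to ribosomal transcripts, or to histone transcripts for the part of the fall that both comparisons share, stays open, because no array has the dyes swapped.

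The second pattern is the smaller rise on replicate 3 of the genes risen most in iaa13: for 145 genes risen at least 4-fold, the median was 3.39 and 2.80 on iaa13 arrays 1 and 2 and 1.85 on array 3, and 1.14, 1.24 and 0.307 on NPA arrays 1, 2 and 3. On the NPA arrays, wild type (Cy5) of replicate 3 held more of these transcripts than replicates 1 and 2 by a median of 0.521, with 127 of 145 genes higher. On the iaa13 arrays, the mutant (Cy3) of replicate 3 held less by a median of -0.763, with 11 of 145 genes higher, and the treated sample (Cy3) of replicate 3 on the NPA arrays also held less, by a median of -0.330 with 26 of 145 genes higher. The values needed by a wild-type and by a mutant cause were both there and both may contribute, but the lower Cy3 level was not confined to the mutant, so a cause common to the samples of replicate 3 stays open. No biological explanation was tested.

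The third pattern is the joint fall of probes that carry a run of at least 6 TG units: 22 of 25 such probes, of 21 genes, were lower in iaa13, with medians of -0.893 with NPA and -1.41 in iaa13, and probes with a run of 8 units had a median of -2.55 in iaa13. Over 7 genes that also have a probe without the repeat, the repeat probes had a median of -0.737 in iaa13 and the other probes 0.231, which is consistent with cross-hybridisation through the repeat in iaa13. With NPA the other probes of these 7 genes had a lower median (-0.580) than the repeat probes (-0.374). For these genes the comparison therefore did not show cross-hybridisation with NPA. Over all 25 repeat probes, however, the NPA median was lower for longer runs: -0.281, -0.935 and -0.969 for 6, 7 and 8 units. Whether the repeat contributes to the NPA values stays open. The repeat probes' medians differed between the comparisons by -0.512, and by -0.572, -0.658 and -0.355 for replicates 1, 2 and 3, which argues against a dye effect equal on all arrays. Which transcripts carry the repeat was not tested.

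Turning the signs of single arrays gave 4 patterns each for NPA and iaa13, of which 1 each, the real one, reached 14250 and 11866 genes; the highest other count was 0 in both. The 6 arrays can be divided into 3 and 3 in 10 ways, of which 1, the real one, reached 8027 genes for the difference, and the highest other was 0. These are too few for a share under 0.05.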

How the results depend on the processing

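The settings that left out both replicate 3 arrays, or probes with repeats or shared sequences, and the lists added later were chosen only after the data or the gene descriptions were seen. For the genes called in both comparisons, the adjusted p under 0.01, the normexp offset of 10, the mean of probes, outlier spots kept, trended and robust variances, only the arrays of the comparison and the random replicate number were not planned either; the other settings were planned. Of 485 results for named genes, 445 kept their direction and their side of the threshold in all settings run, and of 147 list results 100 did, with the estimated correlation among the settings. Over all settings, 84 values of named genes no longer passed, 3 newly passed and 8 reversed; for lists these numbers were 78, 15 and 1.

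The following counts moved by over 1.5 times. With median centring 8383 genes were lower in both comparisons. With the replicate block 2219 genes went in opposite directions, and with a random replicate number 12302 genes differed between iaa13 and NPA. Requiring 2-fold left 2105 genes with NPA, 1007 in iaa13, 1501 for the difference, 192 higher in both, 277 lower in both and 27 opposite, by the construction of the threshold. An adjusted p under 0.01 left 7461 genes in iaa13, 3716 for the difference, 1378 higher in both and 502 opposite. With the correlation estimated, 0 fixed lists passed camera with NPA, 0 in iaa13 and 0 for the difference, and likewise 0 added lists in each. With median centring, 3 added lists in place of 5 passed with NPA and 3 in place of 6 in iaa13.

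Leaving out 1 array in turn gave 11674 to 14237 genes with NPA, 7623 to 11846 in iaa13 and 5257 to 6853 for the difference. It gave 1795 to 2647 genes higher in both, 3272 to 4139 lower in both and 680 to 1151 opposite. The lowest counts in iaa13, for the difference, higher in both and opposite came without iaa13 replicate 2. Fixed lists past the threshold numbered 9 to 10 with NPA, 9 to 11 in iaa13 and 2 to 4 for the difference.

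Reversals came with median centring, except that Os01g0968700 turned to 0.12 for the difference with the mean of its probes. The list of shoot and photosynthesis markers turned to 0.31 in iaa13, Os02g0131800 to -0.14 and Os09g0567400 to -0.11 in iaa13. With NPA, Os02g0626100 turned to -0.11, IAA13 (Os03g0742900) to -0.31, Os07g0186000 to -0.35, Os07g0567700 to -0.12 and Os10g0577900 to -0.22. With median centring the median of all genes lay at -0.19 with NPA and -0.17 in iaa13. The cause was not tested for any of these reversals. Relative to that median, every list called in the report kept its direction. Of the genes called with NPA, 9898 of 14250 were called in the same direction with median centring and 887 in the other; in iaa13 these were 7990 of 11866 and 483.

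The replicate block gave 16193 genes with NPA, 14342 in iaa13 and 11077 for the difference. It ended the calls of expansins with NPA (adjusted p = 0.0581), NAC factors in iaa13 (0.0668) and photosynthesis markers for the difference (0.0698), and IAA13 passed with NPA (0.0208). It changed no other call of a list or named gene given in the report. Median centring also made defence proteins pass with NPA (adjusted p = 0.0427, lowest of 0.0427 to 0.551) and in iaa13 (0.0243, lowest of 0.0243 to 0.718). DUF588 genes passed in iaa13 without NPA replicate 1 (0.0428), NPA replicate 3 (0.0402) or iaa13 replicate 3 (0.0391), in a range of 0.0356 to 0.272. Germin-like proteins passed without iaa13 replicate 1 (0.0273) or iaa13 replicate 3 (0.0391), in a range of 0.0273 to 0.449, and root meristem factors without iaa13 replicate 1 (0.0400, in a range of 0.0400 to 0.479). The stricter filter made germin-like proteins pass for the difference (0.00512, in a range of 0.00512 to 0.431).

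Processed signals, which equal the deposited ratios, gave 14215, 11524 and 7875 genes with NPA, in iaa13 and for the difference. Without probes carrying repeats or shared sequences the counts were 13885, 11605 and 7860, and without both replicate 3 arrays 12894, 10727 and 5676. A fit with the slide as a block was not run, since each slide holds 1 group. Signal over background limits the ratios of dim genes, which are given as bounds. For the other changes of counts and calls in this part the cause was not tested.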

Other observations

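The test of the microRNA probes was chosen after the data were seen, and miR166 and miR398a were singled out after their values were seen. Of 510 probes, 109 were above background. With NPA 35 rose and 17 fell, and in iaa13 5 rose and 2 fell, by limma's adjusted p within these probes.

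Of 24 miR166 probes above background, 22 rose with NPA (median of the family 0.99, highest 1.42) and 0 passed in iaa13 (median -0.03). The difference, iaa13 minus NPA, passed for 23 of them, all lower in iaa13, with a median of -1.01. The probe for the 5' part of miR166a stood at 1.42 ± 0.08 with NPA (adjusted p = 1.05e-05, higher on all 3 arrays). A miR164e probe rose by 1.11 ± 0.16 and a miR171c probe fell to -0.82 ± 0.18. The other miR164 probes above background stood between -0.07 and 0.26 with NPA. Probes for the 5' part of other miR166 members stood at 0.36 (miR166e) and -0.17 (miR166m) with NPA and did not pass. All 3 miR398a probes rose in iaa13, by 1.09 ± 0.36, 1.12 ± 0.47 and 0.89 ± 0.31 (adjusted p from 0.00258 to 0.00365), and did not pass with NPA. Their differences, iaa13 minus NPA, were 0.81 to 0.96 (adjusted p from 0.00431 to 0.00807). The miR398b probes for the 3' part and the mature sequence stood at -0.055 and -0.058 in iaa13 and did not pass (adjusted p = 0.526 and 0.542). How well the probes tell members of a family apart was not tested, so probes of 1 family may not be separate measurements. Whether their signal came from mature microRNAs or from longer precursor transcripts was not tested either.

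Over 3182 genes measured by a second probe, the ratios of both probes correlated across genes, which are not independent replicates, at r = 0.897 with NPA, 0.859 in iaa13 and 0.876 for the difference. Among 37 ribosomal protein genes with such a pair, both probes lay below 0 in 37 with NPA and in 36 in iaa13.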
